A study of Homo sapiens with 6 samples.

How the data were processed

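RNA from A375 melanoma cells was sequenced in 6 libraries, 1 for each combination of a guide (EGFP as control, or COP1) and a treatment (DMSO, 5 nM trametinib or 1 µM vemurafenib for 8 h). The authors deposited 1 table of FPKM (fragments scaled by transcript length and for library depth) for all 6 libraries. Per the submitters' processing notes the values were made with STAR 2.4, Cufflinks 2.2.1 and Cuffnorm on the human genome build hg19. The gene annotation, the filters and the scaling option of Cuffnorm are not given in the sources used here. The table holds named genes with unique symbols, followed by 34929 blank lines that were left out. FPKM scales by transcript length and for library depth, here by a rule that is not given. It shows relative levels and cannot show a change in total RNA per cell. Cuffnorm fits the fragments of overlapping transcripts by a model, so the value of a gene that overlaps another depends on that fit. At least 101 values lay above 0 but far below what any fragment would add.

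Fragment totals are not given in the sources used here, and no counting interval was computed for a gene. The FPKM sums, the numbers of genes at 1 FPKM or more (10735 to 10831) and the share of the 10 most abundant genes (10.2% to 10.8% of the sum) were compared between libraries. The value that 1 fragment adds to a gene was compared between libraries in genes under 0.1 FPKM in every library, which gave depths relative to the EGFP-guide DMSO library of 0.971 to 1.11 for the others. The range of ratios searched was narrowed after a first search had locked onto a ratio of small whole numbers of fragments, and the value for the EGFP-guide vemurafenib library, 0.988, rests on 17 of 62 such genes. No absolute depth can be had from this.

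Values were transformed as log2(FPKM + 1), and the 10803 genes (61.8%) with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, a variance trend and the Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p under 0.05, and all tests were two-sided. The comparisons of guides, of trametinib with DMSO, of vemurafenib with DMSO and of trametinib with vemurafenib came from an additive model of guide and treatment, which leaves 2 residual degrees of freedom (prior 3.97). The difference in inhibitor response between guides and the difference between guides under inhibitor came from a model of guide by inhibition, in which both inhibitors count as inhibition (2 residual degrees of freedom, prior 4.08). With 1 library per combination the p-values measure spread among libraries of different treatments, not among replicate cultures. The additive model counts any interaction of guide and treatment as noise, and the other model counts any difference between the inhibitors as noise. SE is limma's moderated standard error, with a median of 0.069 for the guides, 0.085 for an inhibitor, 0.096 for the guides under inhibitor and 0.17 for the interaction.

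The fits were tested on simulated data of 10803 genes with 200 changed. Changes of 0.58, 1 and 2 on the log2 scale were recovered at 85.1%, 95.5% and 100% between guides, 62.7%, 95.5% and 100% for trametinib, 68.7%, 95.5% and 100% for vemurafenib, and 52.2%, 95.5% and 97.0% between guides under inhibitor. For the interaction the rates were 2.99%, 28.4% and 90.9%, so a difference in response of 1 would mostly be missed. Between 4.10% and 12.0% of the simulated calls were false, the highest for the interaction, against the 5% that the adjustment aims at. The simulated noise was drawn from the variance prior of the fit, after a first version drawn from already moderated variances had held too little spread. Simulated changes followed the fitted model, so in the additive one they held no interaction of guide and treatment. The rates hold only for changes of that form. Between guides 13 genes at least 2-fold higher were called, but SPRY2 (1.33) and LIF (1.23) were not.

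Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists within a comparison, and again with an estimated correlation and with fry. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. No list passed with an estimated correlation in any comparison. That form of camera rests on the residual degrees of freedom, 2 here, so hardly any list could pass it. The immediate-early list under trametinib had an estimated correlation of -0.024, under the preset 0.01. Its camera adjusted p still went from 3.91e-06 to 0.175. These p-values therefore do not tell whether correlation between genes made a call. Fry called 0 lists between guides, 14 for trametinib, 12 for vemurafenib, 0 for the inhibitors against each other, 0 for the interaction and 3 between guides under inhibitor. The lists were ERK feedback, other ERK output, immediate-early factors, ETS factors, COP1 complex, COP1 substrates, AP-1 and ETS invasion genes, ribosome biogenesis, S phase, mitosis, cell-cycle inhibitors, p53 targets, pigmentation, dedifferentiation, receptor tyrosine kinases, apoptosis regulators, ATF4 and unfolded protein response, cholesterol, glycolysis, oxidative phosphorylation, hypoxia, interferon, NF-kB and cytokines, lysosome and autophagy, heat shock, histones, mitochondrially encoded, housekeeping, immune cell, epithelial and fibroblast markers. Of their 612 symbols 598 were in the table and 528 were tested. Some genes stand in more than 1 list, such as LIF, PLAUR and PFKFB4, so the lists are not independent. List medians were also set against 10000 random lists matched on expression in 20 bins. For the retained output, genes changed by at least 1 log2 unit with 1 inhibitor in EGFP-guide cells were read as COP1-minus-EGFP differences under the other inhibitor. No test was made, and the difference between guides under DMSO was not subtracted.

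The groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the targeted gene, the 10 largest passing changes each way between guides and for the interaction (filled with genes of the largest matched differences where fewer passed, and said not to have passed), the 5 largest each way for each inhibitor, up to 4 members of each list with the largest change, and DUSP6, SPRY2, SPRY4, ETV1, ETV4, ETV5, CCND1, EGR1, FOSL1, PHLDA1, MYC and JUN. Genes needed the same sign in every matched difference, and small RNAs and read-through genes were left out. Genes named beyond this rule, such as the remaining members of a small count, were chosen after their values were seen. The alternatives were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, rescaling of each library by its median ratio (factors 0.995 to 1.01), moderation without a trend, no treatment term, leaving out each library in turn, and, for the retained output, a threshold of 0.58 log2 units in place of 1. Refits without each library of the 8 lists called for the interaction were added after the data had been seen. Positions are not given, since the annotation at hand is on GRCh38.p14 and not on hg19; it served only to find neighbours and overlaps of genes, for the 99.0% of tested genes that it could be matched to. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.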

Results

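RNA was sequenced from A375 cells, a human melanoma line with an activating BRAF mutation, that carried a CRISPR guide against COP1 or a control guide against EGFP. COP1 is an E3 ubiquitin ligase, listed in the deposited table under its older symbol RFWD2. Cells of each guide were treated for 8 h with DMSO, with 5 nM trametinib (a MEK inhibitor) or with 1 µM vemurafenib (a BRAF inhibitor). The protocol text in the labels describes an siRNA transfection of 48 h before the drug, whereas the sample fields name a CRISPR guide, and which of them applies is not given in the sources used here. There was 1 library for each guide and treatment, 6 in all, so no combination had a replicate. The spread behind the errors below is that between libraries after the effects of guide and treatment were taken out, or, for the interaction and for the guides under inhibitor, after those of guide and inhibition, which leaves differences between the 2 inhibitors in it. Fragment totals are not given in the sources used here, so the depth of the libraries is unknown. The FPKM values of a library summed to between 606990 and 626872, and 10735 to 10831 named genes reached 1 FPKM.

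The transcript of the targeted gene was lower in COP1-guide cells under every treatment. RFWD2 (ENSG00000143207) was at 46.2 FPKM with DMSO, 44.6 with trametinib and 51.2 with vemurafenib in EGFP-guide cells. In COP1-guide cells the matching values were 17.8, 19.3 and 17.4 FPKM. The transcript fell by 1.34 on the log2 scale (SE 0.075, adjusted p = 0.00764, lower in 3 of 3 treatment-matched differences). Its response to the inhibitors was 0.029 with trametinib and 0.055 with vemurafenib, neither past the test, and these turned to -0.095 without the COP1-guide trametinib library and to -0.073 without the EGFP-guide vemurafenib library.

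Trametinib was compared with DMSO to ask which transcripts depend on MEK activity in these cells. The largest changes were losses of feedback inhibitors of the ERK pathway. The ERK phosphatase DUSP6 (ENSG00000139318) went from 100.2 to 1.72 FPKM in EGFP-guide cells and from 192 to 10.3 FPKM in COP1-guide cells, a log2 change of -4.65 (SE 0.24, adjusted p = 0.00156). The ERK pathway inhibitor SPRY4 (ENSG00000187678) changed by -4.36 (SE 0.12, adjusted p = 0.000298) and SPRY2 by -2.70 (SE 0.40, adjusted p = 0.0294). PHLDA1 fell by 2.96 (SE 0.18) and CSF2, which encodes the cytokine GM-CSF, fell by 2.70 (SE 0.22). Of the genes that rose, the transcription factors SOX2 (1.52, SE 0.11) and FOXD3 (1.24, SE 0.080), FAM46A (1.42, SE 0.13), the phosphoinositide phosphatase MTM1 (1.22, SE 0.12) and TXNIP (1.14, SE 0.10) rose most. Each of these 10 genes moved one way with both guides, in 2 of 2 differences, as the naming rule required. In all, 254 of 10803 tested genes passed, 23 of them higher and 231 lower. Without a filter on low values the count was 32, and SOX2, FAM46A, MTM1, TXNIP, PHLDA1, SPRY2 and CSF2 were not among them (adjusted p from 0.0506 for PHLDA1 to 0.203 for SPRY2). SPRY2 did not pass without a variance trend either (adjusted p = 0.0551). It was 126 without the EGFP-guide DMSO library, 74 without the EGFP-guide trametinib library, 167 without the COP1-guide DMSO library and 77 without the COP1-guide trametinib library, and SPRY2 (-2.32 and -3.09) did not pass without either trametinib library, CSF2 (-2.52) without the EGFP-guide one, and FAM46A (1.26) and TXNIP (1.06) without the COP1-guide one.

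Gene groups fixed beforehand showed where the trametinib response lay. Of 12 negative feedback regulators of ERK, 8 fell, or 11 adjusted over the list alone, with a median log2 change of -1.41 (camera adjusted p = 1.59e-18, and 0.175 with an estimated correlation). Of 28 other genes driven by ERK in BRAF-mutant cells, 16 fell, or 21 adjusted over the list alone (median -0.82), among them PHLDA1, the cytokine LIF (-2.70), the transcription factor EGR1 (-2.44) and IL1B (-2.34). CCND1, which encodes cyclin D1, fell by 0.84 and FOSL1 fell by 0.88, whereas MYC was at -0.79 and did not pass. Without a filter on low values CCND1, EGR1 and FOSL1 did not pass (adjusted p of 0.0598, 0.0678 and 0.0668). Without the EGFP-guide trametinib library CCND1 (-0.83), EGR1 (-2.38) and FOSL1 (-0.90) did not pass, and without the COP1-guide trametinib library EGR1 (-2.49) and FOSL1 (-0.85) did not, while MYC passed at -1.27 without the COP1-guide DMSO library and at -0.79 without either vemurafenib library. Of 18 NF-kB targets and cytokines, 9 fell, or 17 adjusted over the list alone (median -0.84), including LIF, IL1B, IL1A (-2.07) and IL11 (-1.64). Of 24 immediate-early transcription factors, 11 fell and 1 rose, or 14 and 3 adjusted over the list alone (median -0.55). FOS (-1.64) and EGR3 (-1.12) fell, ATF3 rose (1.01), and JUN was at 0.27 without passing. Among 16 ETS factors, ELK3 (-0.57), ETV3 (-0.48) and ETS1 (-0.48) fell, 3 in all and 8 adjusted over the list alone (median -0.24), while ETV1 was at -0.34, ETV4 at -0.089 and ETV5 at -0.38, none past the test. Among 18 apoptosis regulators 4 fell, or 5 with 1 higher adjusted over the list alone: the pro-apoptotic PMAIP1 (-1.38) and the pro-survival MCL1 (-0.99), BIRC3 (-0.80) and BCL2L1 (-0.63). The adjusted p was 0.175 with an estimated correlation for the feedback, ERK output, NF-kB, immediate-early and ETS lists and 0.309 with an estimated correlation for the apoptosis list.

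Camera placed 18 of the 31 lists past its threshold for trametinib, 14 lower and 4 higher. None of the 18 passed with an estimated correlation, a form that has only 2 degrees of freedom here. The other lower lists were invasion and protease genes (2 of 16 fell, 4 adjusted over the list alone, median -0.15), glycolysis (2 of 19, 6 adjusted over the list alone, -0.085) and hypoxia-induced genes (3 of 12, 5 with 1 higher adjusted over the list alone, -0.23), with adjusted p of 0.175, 0.175 and 0.244 with an estimated correlation. The glycolysis members ENO2 (-0.69) and SLC2A3 (-0.57) and the hypoxia members ANGPTL4 (-0.74) and VEGFA (-0.73) fell. In the list of the COP1 ligase and its adaptors, which include the Tribbles pseudokinases, TRIB1 (-1.51) and TRIB2 (-0.58) fell, 2 of 11 by either adjustment (median -0.030, adjusted p = 0.318 with an estimated correlation). Genes whose proteins are reported COP1 substrates gave 2 of 13, CEBPB (-0.61) and ETS1, or 4 adjusted over the list alone (median -0.089, adjusted p = 0.345 with an estimated correlation). Pigmentation genes had 0 of 11 members past the test over all genes and 3 lower adjusted over the list alone (median -0.16), and receptor tyrosine kinases and ligands had 1 of 20, EPHA2 (-1.40), and 3 adjusted over the list alone (median -0.063). TYR, TYRP1, DCT and other listed pigmentation genes had a mean under 1 FPKM and were not tested, so that median leaves them out. Dedifferentiation genes had 3 of 18 lower, among them CTGF (-0.89), 4 lower adjusted over the list alone, and 1 higher by either adjustment, SOX2 (median -0.12), and for these 3 lists the adjusted p was 0.244 with an estimated correlation. The lists called higher were DNA replication (median 0.065, adjusted p = 0.244 with an estimated correlation), mitosis (0.10, 0.318), oxidative phosphorylation (0.048, 0.673) and replication-dependent histones (0.14, 0.324). No member of them passed over all genes, and 2 mitosis genes and 1 histone rose adjusted over the list alone. The mitosis call was lost without the COP1-guide trametinib library (median 0.045) and the histone call without the EGFP-guide DMSO library (0.073) or the EGFP-guide trametinib library (0.12).

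Vemurafenib, which acts one step above MEK on mutant BRAF, was compared with DMSO in the same way. DUSP6 went from 100.2 to 1.11 FPKM with the EGFP guide and from 192 to 5.13 FPKM with the COP1 guide, a log2 change of -5.28 (SE 0.24, adjusted p = 0.000719). SPRY4 changed by -4.85 (SE 0.12, adjusted p = 0.000158), PHLDA1 by -3.04 (SE 0.18), CSF2 by -2.92 (SE 0.22) and SPRY2 by -2.90 (SE 0.40, adjusted p = 0.0188). SOX2 (1.74, SE 0.11), FOXD3 (1.53, SE 0.080), FAM46A (1.47, SE 0.13) and the transcription factor NFIL3 (1.41, SE 0.11) rose. ZNFX1 rose most, by 3.13 (SE 0.38), with uneven values of 13.3, 42.5 and 91.0 FPKM for DMSO, trametinib and vemurafenib with the EGFP guide and 12.7, 20.6 and 161 FPKM with the COP1 guide, and its residual SD was at least 0.65 log2 units in both models, where the median gene had 0.065. All 10 genes moved one way with both guides, as the naming rule required. In all, 350 genes passed, 60 higher and 290 lower. Without a filter on low values the count was 81, and ZNFX1 (adjusted p = 0.120), FAM46A (0.0591) and SPRY2 (0.144) did not pass, nor did EGR1 (0.0588), FOSL1 (0.0588) and ETV1 (0.0710). The count was 150 without the EGFP-guide DMSO library and 232 without the EGFP-guide vemurafenib library.

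For vemurafenib, 9 lists passed with camera, and none did with an estimated correlation. Among ERK feedback regulators 9 of 12 fell, or 12 adjusted over the list alone (median -1.38), and among other ERK-driven genes 17 of 28 fell, or 22 adjusted over the list alone (median -0.82). The second group included LIF (-2.51), EGR1 (-2.42), IL1B (-2.18), CCND1 (-0.90) and FOSL1 (-0.86), with MYC at -0.86 and not past the test. NF-kB targets and cytokines had 9 of 18 lower, or 14 adjusted over the list alone (median -0.73), including CXCL3 (-2.06) and IL1A (-2.12). Immediate-early factors had 12 of 24 lower and 1 higher, or 15 and 7 adjusted over the list alone (median -0.74), with FOS at -1.63, FOSB at -1.11 and ATF3 at 0.98, and JUN at 0.46 without passing. ETS factors had 4 of 16 lower, or 6 adjusted over the list alone (median -0.20), and these were ELK3 (-0.67), ETV3 (-0.60), ETS1 (-0.50) and ETV1 (-0.48), with ETV4 at -0.071 and ETV5 at -0.36 not past the test. ETV1 did not pass without the EGFP-guide DMSO (-0.49), EGFP-guide vemurafenib (-0.52), COP1-guide DMSO (-0.47) or COP1-guide vemurafenib (-0.44) library, whereas without the COP1-guide DMSO library MYC (-1.34) and JUN (0.73) passed, as did MYC (-1.27) without the COP1-guide vemurafenib library. The adjusted p for these 5 lists was 0.236 with an estimated correlation. Invasion genes (2 of 16 lower, 5 adjusted over the list alone, median -0.17) and hypoxia genes (2 of 12 by either adjustment, median -0.13) were also lower, and DNA replication genes (median 0.11) and histones (median 0.25) higher, with no replication gene or histone past the test over all genes and 2 histones adjusted over the list alone. Their adjusted p with an estimated correlation was 0.236, 0.510, 0.283 and 0.432. The hypoxia call was lost without the EGFP-guide DMSO library (median -0.0068) or the EGFP-guide vemurafenib library (-0.11), and the histone call without the EGFP-guide DMSO library (0.17). Among apoptosis regulators, which camera did not call (median 0.043, mean -0.14, adjusted p = 0.420), PMAIP1 fell by 1.59 and MCL1 fell by 1.17, and the pro-apoptotic BMF rose by 1.14.

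The MEK and BRAF inhibitors were then set against each other. By limma 0 genes passed, with 889 at an unadjusted p under 0.05 where 540 are expected by chance, and the smallest adjusted p was 0.172. The count was 5 without the EGFP-guide vemurafenib library and 16 without the COP1-guide vemurafenib library. MTM1, named for its rise with trametinib, was at 5.91, 17.2 and 6.07 FPKM for DMSO, trametinib and vemurafenib with the EGFP guide and 5.06, 11.5 and 5.25 FPKM with the COP1 guide, and its trametinib-minus-vemurafenib difference was 1.18 (SE 0.12, adjusted p = 0.190). Camera called none of the 31 lists, and neither camera with an estimated correlation nor fry did. Without the COP1-guide vemurafenib library the ERK feedback (median 0.14), ERK output (0.097) and mitochondrially encoded lists (0.35) were called, without the EGFP-guide vemurafenib library the mitochondrial list (-0.37), without the EGFP-guide trametinib library the mitosis list (0.099) and without the COP1-guide trametinib library the heat-shock list (-0.092). Of the 231 genes lower with trametinib and the 290 lower with vemurafenib, 194 were shared, where 6.20 would be shared by independent draws, and of the 23 and 60 higher genes 21 were shared, against 0.128. Both contrasts use the same DMSO libraries, which alone gave a correlation of 0.501 across genes in 100 simulated data sets with no effect. The measured correlation was 0.826. The simulated sets gave no shared calls, but with no effect there is next to nothing to call. They cannot show how many of the 194 and 21 shared calls come from the shared libraries or the shared error of each gene. Responses that share no library also went together across genes: that to trametinib with the EGFP guide and that to vemurafenib with the COP1 guide had Pearson's r of 0.608 and Spearman's rho of 0.481 over 10803 genes, which are not independent replicates, and that to vemurafenib with the EGFP guide and that to trametinib with the COP1 guide had r of 0.475 and rho of 0.194.

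The comparison of COP1-guide with EGFP-guide cells, blocked by treatment, asked what loss of COP1 does to these transcripts. Several ERK feedback genes were among those that rose most. SPRY1 (ENSG00000164056) was at 6.36, 0.837 and 0.997 FPKM for DMSO, trametinib and vemurafenib with the EGFP guide and 14.9, 9.18 and 8.18 FPKM with the COP1 guide, a log2 change of 1.93 (SE 0.25, adjusted p = 0.0376). The ERK phosphatases DUSP5 (ENSG00000138166; 1.56, SE 0.21, adjusted p = 0.0401) and DUSP6 (1.51, SE 0.20, adjusted p = 0.0376) rose as well. The collagen-binding integrin subunit ITGA1 (ENSG00000213949) rose by 1.52 (SE 0.074, adjusted p = 0.00764), from 25.2 to 67.8 FPKM with DMSO. The iron-storage gene FTH1 (ENSG00000167996), one of the most abundant transcripts, fell by 0.72 (SE 0.052, adjusted p = 0.0120), from 1686 to 1103 FPKM with DMSO. In all, 148 genes passed, 101 higher and 47 lower, of which 13 rose and 1 fell at least 2-fold. The count was 0 without a filter on low values (2433 at an unadjusted p under 0.05 by limma), 31 without a variance trend and 24 without the treatment term. Without a variance trend SPRY1 (adjusted p = 0.0656), DUSP5 (0.0671) and DUSP6 (0.0656) did not pass. It was 3 without the EGFP-guide trametinib library, 2 without the COP1-guide trametinib library and 92 without either vemurafenib library, and of the 20 genes named here only RFWD2 and ITGA1 passed in each of the 6 refits that leave out 1 library.

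The other named genes that rose with the COP1 guide were the metastasis suppressor KISS1 (1.51, SE 0.18), the transcription factors IKZF2 (1.37, SE 0.081) and HOXB8 (1.13, SE 0.071), the BMP antagonist NOG (1.20, SE 0.18), the kinase BMX (1.16, SE 0.10) and the cytidine deaminase APOBEC3G (1.15, SE 0.061). Their adjusted p ran from 0.00764 for APOBEC3G to 0.0441 for NOG, and NOG no longer passed with a pseudocount of 0.1 or after the libraries were rescaled. Those that fell were the adhesion molecules CEACAM1 (-0.88, SE 0.12) and ITGB7 (-0.78, SE 0.081), FAM46A (-0.84, SE 0.11), the oxidative stress gene OSGIN1 (-0.73, SE 0.093), the transcription factor MAF (-0.68, SE 0.10), ZNF608 (-0.67, SE 0.066), the collagen COL15A1 (-0.65, SE 0.10) and the ephrin EFNA1 (-0.64, SE 0.062). Each of these genes moved one way in 3 of 3 treatment-matched differences, as the naming rule required. Without a variance trend KISS1, NOG, CEACAM1, FAM46A, OSGIN1, MAF and COL15A1 did not pass by limma (adjusted p from 0.0622 for KISS1 to 0.0707 for MAF). Without the treatment term IKZF2, NOG, BMX, HOXB8, FAM46A, OSGIN1, MAF, ZNF608, COL15A1 and EFNA1 did not (0.0837 for OSGIN1 to 0.573 for EFNA1). The PEA3 factors, whose proteins are COP1 substrates, were at -0.031 (ETV1), -0.079 (ETV4) and 0.049 (ETV5), EGR1 at 0.050, CCND1 at 0.25, FOSL1 at 0.24 and JUN at -0.36, none past the test. Without either DMSO library ETV5 was at -0.0052 and EGR1 at -0.15, while SPRY2 (1.89), MYC (1.25), PHLDA1 (0.82) and JUN (-0.54) passed.

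For the COP1 guide, camera called 7 lists, all higher, and for each the adjusted p was 0.495 with an estimated correlation. Of 12 ERK feedback regulators 4 rose, or 8 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 1.02e-06), and the fourth after SPRY1, DUSP5 and DUSP6 was the adaptor SH2B3 (0.68). Of 28 other ERK-driven genes 3 rose, or 13 with 3 lower adjusted over the list alone (median 0.16). The risers were HMGA2 (0.39), PLAUR (0.53) and SLC20A1 (0.51), while LIF (1.23), EPHA4 (1.20), MYC (0.94) and PHLDA1 (0.58) had larger values that did not pass. Of 16 invasion and protease genes 5 rose, or 8 with 2 lower adjusted over the list alone (median 0.20), among them the proteases MMP9 (0.59) and ADAM19 (0.47), the urokinase receptor PLAUR and the integrin ITGA2 (0.49). Hypoxia-induced genes (1 of 12 rose, 9 adjusted over the list alone, median 0.25) and glycolysis genes (1 of 19 rose, 8 adjusted over the list alone, median 0.078) shared their only riser, PFKFB4 (0.46). Mitosis genes (median 0.12) and NF-kB targets (median 0.20) had 0 members past the test over all genes and 4 of 28 and 6 of 18 higher adjusted over the list alone, with KIF11 at 0.28 and IL6 at 0.63. ETS factors (median -0.015) and genes of COP1 substrates (median -0.031, mean -0.033, while camera gave the direction up) were not called, with camera adjusted p of 0.876 and 0.812. Mitochondrially encoded genes had a median of -0.0019 over the 3 treatments, called higher without either DMSO library (0.18) and lower without either vemurafenib library (-0.24), and histones (-0.18, not called) were called lower without either DMSO library (-0.20). Of the 101 genes that rose with the COP1 guide, 27 were among those that fell with trametinib and 31 among those that fell with vemurafenib, where independent draws would give 2.16 and 2.71, and 0 were among the genes that rose with either inhibitor. The 47 genes that fell with the COP1 guide overlapped both ways: 6 fell and 6 rose with trametinib (1.00 and 0.10 by independent draws), and 5 fell and 8 rose with vemurafenib (1.26 and 0.261). These comparisons come from 1 fit, with 1 error variance for each gene. Genes of small spread are thus more readily called in each of them, so independent draws set too low a reference for these overlaps.

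**Figure D1:**
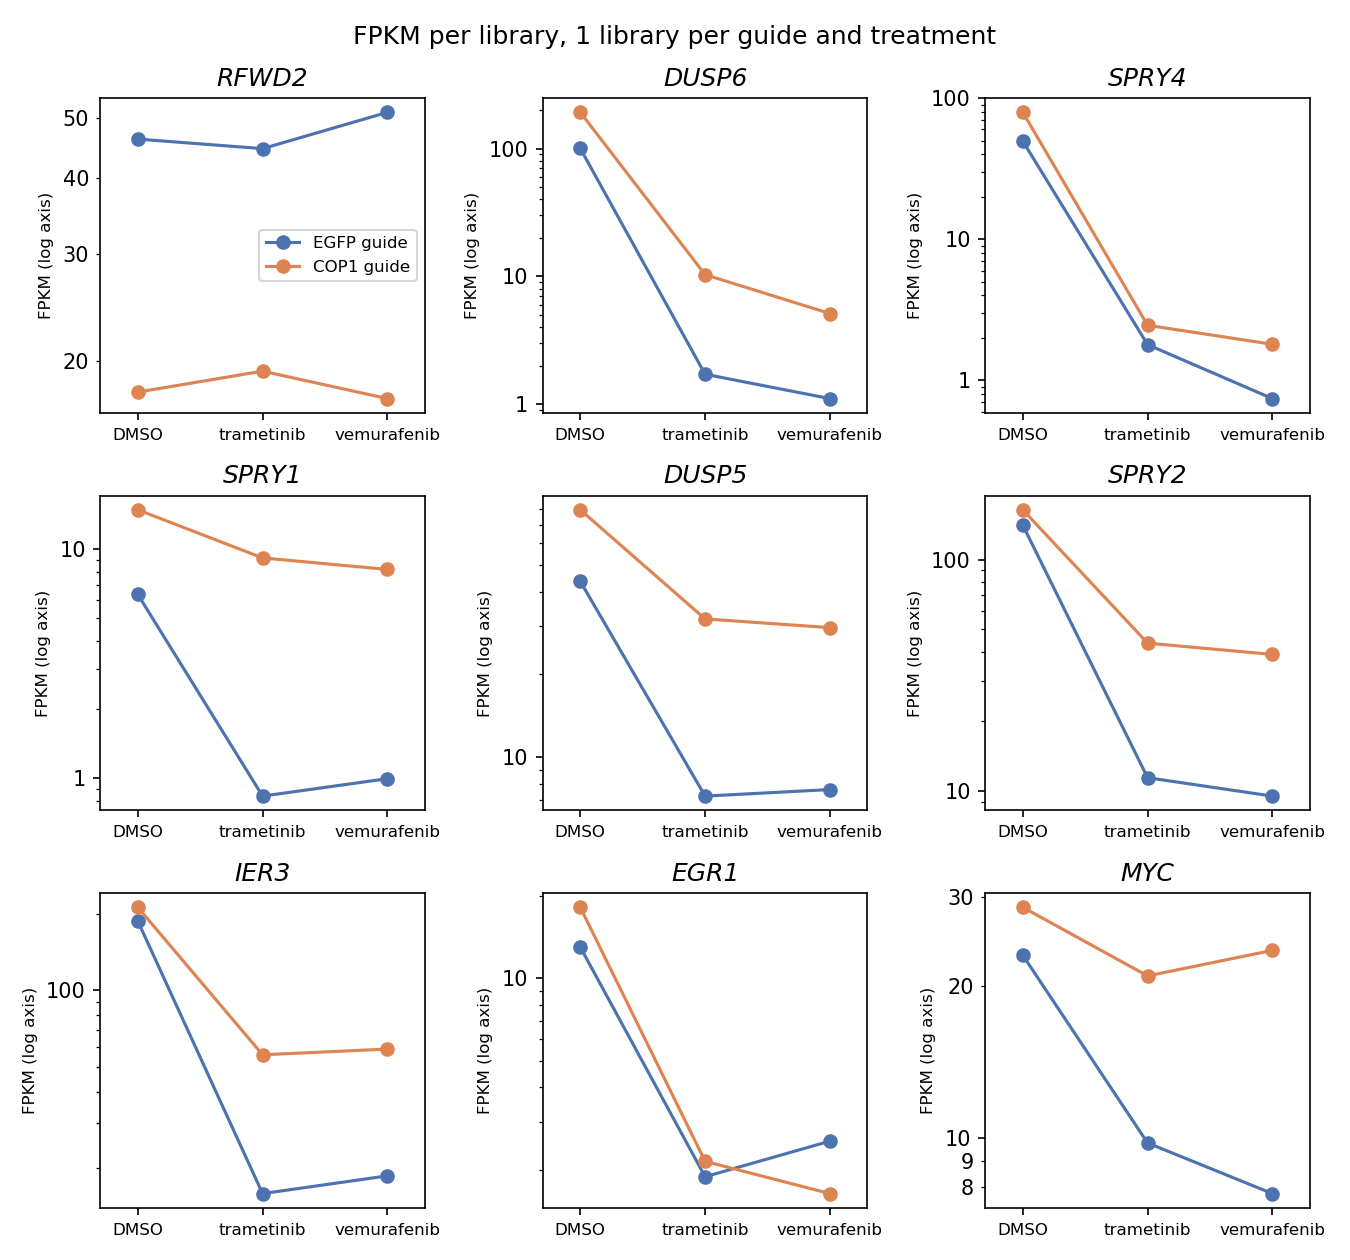
FPKM of 9 genes in each of the 6 libraries on log axes, by treatment, with 1 point per library and a line per guide. RFWD2 lies at 44.6 FPKM or more with the EGFP guide and at 19.3 FPKM or less with the COP1 guide, and DUSP6 lies at 1.11 FPKM with vemurafenib and the EGFP guide against 5.13 FPKM with the COP1 guide.

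Under the inhibitors, 5 of 12 ERK feedback transcripts were higher in COP1-guide than in EGFP-guide cells by limma, and the list as a whole had an adjusted p of 0.463 with an estimated correlation and 0.0372 with fry. SPRY1 was higher by 2.34 (SE 0.11, adjusted p = 0.00304), DUSP5 by 1.92 (SE 0.081, adjusted p = 0.00304) and SPRY2 by 1.89 (SE 0.11, adjusted p = 0.00406) over 2 inhibited libraries of each guide. The YAP target ANKRD1 (1.73, SE 0.13), the early response gene IER3 (1.68, SE 0.093), the ephrin receptor EPHA4 (1.66, SE 0.10), LIF (1.63, SE 0.11) and MYC (1.25, SE 0.12) were higher too. DUSP6 was at 1.80 (SE 0.29) with an adjusted p of 0.0881 and SPRY4 at 0.50 with 0.409, and neither passed. RFWD2 fell by 1.34 (SE 0.10, adjusted p = 0.00892). In all, 47 genes passed, 39 higher and 8 lower, of which 23 and 6 were also called over all treatments, a comparison that uses the same inhibited libraries. The count was 0 without a filter on low values (1795 at an unadjusted p under 0.05 by limma) and 30 without a variance trend. It was 0 without either inhibited COP1-guide library, 136 without the EGFP-guide trametinib library and 101 without the EGFP-guide vemurafenib library.

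By list, 5 of 12 ERK feedback regulators were higher with the COP1 guide under the inhibitors, or 7 adjusted over the list alone (median 0.57, camera adjusted p = 1.85e-11), and 5 of 28 other ERK-driven genes, or 13 with 3 lower adjusted over the list alone (median 0.23). The latter were EPHA4, LIF, MYC, PHLDA1 (0.82) and PLAUR (0.61). NF-kB targets (1 of 18, LIF, and 5 adjusted over the list alone, median 0.29), invasion genes (1 of 16, PLAUR, and 7 with 2 lower adjusted over the list alone, median 0.21) and hypoxia genes (0 of 12, and 5 adjusted over the list alone, median 0.26) were called higher as well. For these 5 lists the adjusted p was 0.463 with an estimated correlation. Fry called 3 lists, each at an adjusted p of 0.0372: ERK feedback higher, and ribosome biogenesis (median -0.049) and the COP1 ligase with its adaptors lower, a list of 11 genes (median -0.0085, mean -0.12) that holds RFWD2 itself, its only member past the test over all genes. Mitosis (median 0.14), receptor tyrosine kinase (0.074), glycolysis (0.055) and mitochondrially encoded genes (0.18) were called higher and histones (-0.20) lower, with an adjusted p of 0.536 with an estimated correlation. Over all genes EPHA4 alone of their members passed, and adjusted over the list alone 3 receptor genes, 3 glycolysis genes, 4 mitochondrial genes and 1 histone were higher and 5 histones lower. Without either vemurafenib library the mitochondrial call was lost (median 0.067 without the EGFP-guide one and 0.075 without the COP1-guide one), and the histone call was lost without the EGFP-guide vemurafenib library (-0.21) or the COP1-guide trametinib library (-0.18).

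Genes chosen for their response to one inhibitor were next read under the other, so that no library served for both choice and measurement. Of 102 genes at least 1 log2 unit lower with vemurafenib in EGFP-guide cells, 79 (77.5%, exact 95% binomial interval 68.1% to 85.1%) had more transcript with the COP1 guide than with the EGFP guide under trametinib, with a median log2 difference of 0.29. Of 86 genes chosen by trametinib, 66 (76.7%, interval 66.4% to 85.2%) had more under vemurafenib, with a median of 0.41. The difference between guides under DMSO was not subtracted, so a gene already higher with the COP1 guide under DMSO counts here. With DMSO, 10 of 12 ERK feedback genes were higher with the COP1 guide, with a median of 0.26. Medians of 10000 random lists matched on expression lay between -0.10 and 0.11 for the 102 genes and between -0.095 and 0.075 for the 86. With a threshold of 0.58 log2 units in place of 1 the medians were 0.16 and 0.19, with 68.4% and 71.7% of genes above 0. Of the 29 genes raised by vemurafenib 10 were above 0 (interval 17.9% to 54.3%, median -0.32), and of the 14 raised by trametinib 6 were (interval 17.7% to 71.1%, median -0.31, quartiles -0.82 and 0.77), and both intervals cover 50%. Medians of random lists lay between -0.21 and 0.16 for the 29 genes, so that their median was under all 10000, and between -0.32 and 0.25 for the 14, whose median was above 0.01% of them. With a pseudocount of 0.1 these 2 medians were -0.15 and -0.18, without a filter the second was -0.18, and with the threshold of 0.58 they were -0.18 and -0.15. With that threshold 35.8% of 165 genes and 36.3% of 102 were above 0 (intervals 28.5% to 43.6% and 27.0% to 46.4%), and without a filter 31.4% of the genes raised by vemurafenib were (16.9% to 49.3%), so these 3 intervals lie under 50%. Genes are not independent of one another, so the intervals cover counting error only. SPRY1 kept 13.1% of its DMSO level under trametinib and 15.7% under vemurafenib with the EGFP guide, and 61.6% and 54.9% with the COP1 guide. EPHA4 kept 29.3% and 28.0% against 86.0% and 95.3%, and SPRY2 8.10% and 6.74% against 26.5% and 23.7%. EGR1 kept 14.6% and 19.6% with the EGFP guide and 11.9% and 9.06% with the COP1 guide, and SPRY4 3.61% and 1.50% against 3.10% and 2.27%.

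**Figure D2:**
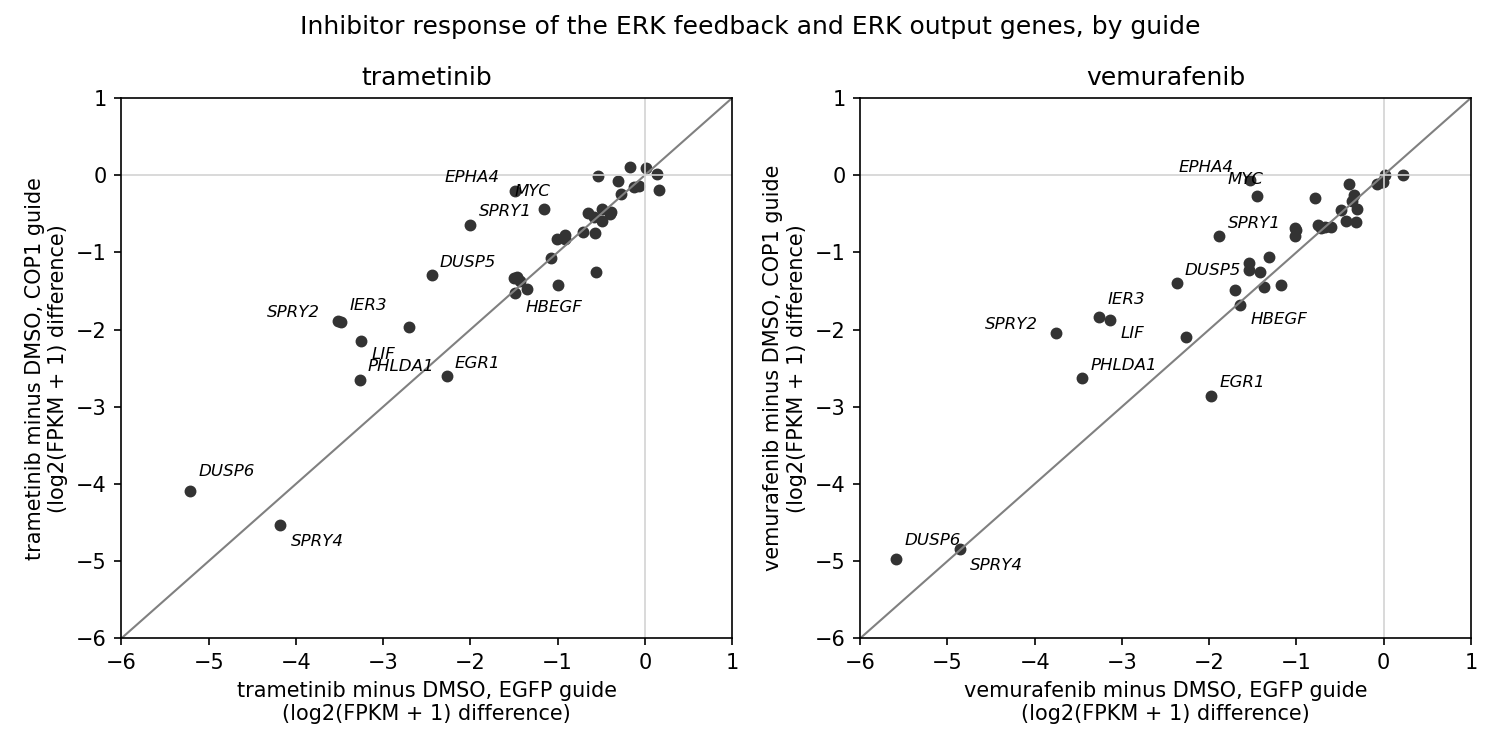
Inhibitor minus DMSO difference in log2(FPKM + 1) of the ERK feedback and ERK output genes, with the EGFP guide on the x axis and the COP1 guide on the y axis, 1 panel per inhibitor and 1 point per gene, with the line of equal response. SPRY2, IER3, LIF and EPHA4 lie above the line in both panels and EGR1 lies below it.

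Whether the response to the inhibitors differed between guides was tested directly as an interaction, with both inhibitors counted as inhibition. SPRY2 had the largest value of an ERK feedback gene, with a log2 difference in response of 1.67 (SE 0.19, adjusted p = 0.528), followed in size by IER3 (1.50, SE 0.16) and SPRY1 (1.23, SE 0.19), and none passed. EPHA4 (1.38), ANKRD1 (1.28) and LIF (1.19) lay on the same side, as did ADAT2 (3.88), UBAP2 (1.39), MADD (1.32) and LYSMD3 (1.15). On the other side lay C11orf70 (-4.28), WDR78 (-2.14), the acetylcholinesterase gene ACHE (-1.69), the histone gene HIST1H2AM (-1.54), CRIP1 (-1.18), GPR157 (-1.17), CDR1 (-1.16), C1orf122 (-1.08), SVIL (-1.07) and DOK7 (-0.95). None of these 20 genes passed. By limma 0 genes passed, 324 had an unadjusted p under 0.05 where 540 are expected by chance, and the smallest adjusted p was 0.528. The count was 9 without the EGFP-guide trametinib library and 9 without the EGFP-guide vemurafenib library, both including SPRY2 (1.79 and 1.55), IER3 (1.39 and 1.61) and C11orf70 (-4.48 and -4.08), and the first also EPHA4 (1.40), ANKRD1 (1.42), ACHE (-1.93) and WDR78 (-3.29).

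In the same test camera called 8 lists, 7 of them with a positive difference in response (COP1 guide minus EGFP guide), and for each the adjusted p was 0.883 with an estimated correlation. Fry called none of them, with adjusted p of 0.675 for ERK feedback and 0.720 for ERK output. ERK feedback regulators had a median difference in response of 0.21 with 0 of 12 past the test over all genes and 4 adjusted over the list alone, and other ERK-driven genes 0.056 with 0 of 28 and 4, led by EPHA4, LIF, MYC (0.95) and PHLDA1 (0.72). Mitochondrially encoded genes changed by a median of -0.085 and -0.36 with trametinib and vemurafenib in EGFP-guide cells and by 0.28 and 0.57 in COP1-guide cells, and had the largest median difference, 0.63 (0 of 12, and 8 adjusted over the list alone), with MT-ND6 at 0.84 and MT-ND1 at 0.71. Mitosis (0.061), hypoxia (0.093), NF-kB (0.084) and heat-shock genes (0.088) had smaller medians, with 1 NF-kB gene past the test adjusted over the list alone. Histones were lower, with a median of -0.12 and 1 higher and 3 lower adjusted over the list alone, with HIST1H4C at 1.13 and HIST2H2AC at -1.08. Of these lists only ERK feedback, ERK output and mitochondrially encoded genes were called in each of the 4 refits that leave out 1 inhibited library. The mitosis call was lost in 3 of them (medians 0.074, 0.053 and 0.037 without the EGFP-guide trametinib, EGFP-guide vemurafenib and COP1-guide trametinib libraries) and the heat-shock call in 3 (0.066, 0.10 and 0.078 without the EGFP-guide trametinib, EGFP-guide vemurafenib and COP1-guide vemurafenib libraries). The NF-kB call was lost without the EGFP-guide trametinib (0.10) or COP1-guide trametinib library (0.029), the hypoxia call without the EGFP-guide trametinib (0.076) or COP1-guide vemurafenib library (-0.00031), and the histone call without the EGFP-guide vemurafenib (-0.11) or COP1-guide trametinib library (-0.15).

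**Figure D3:**
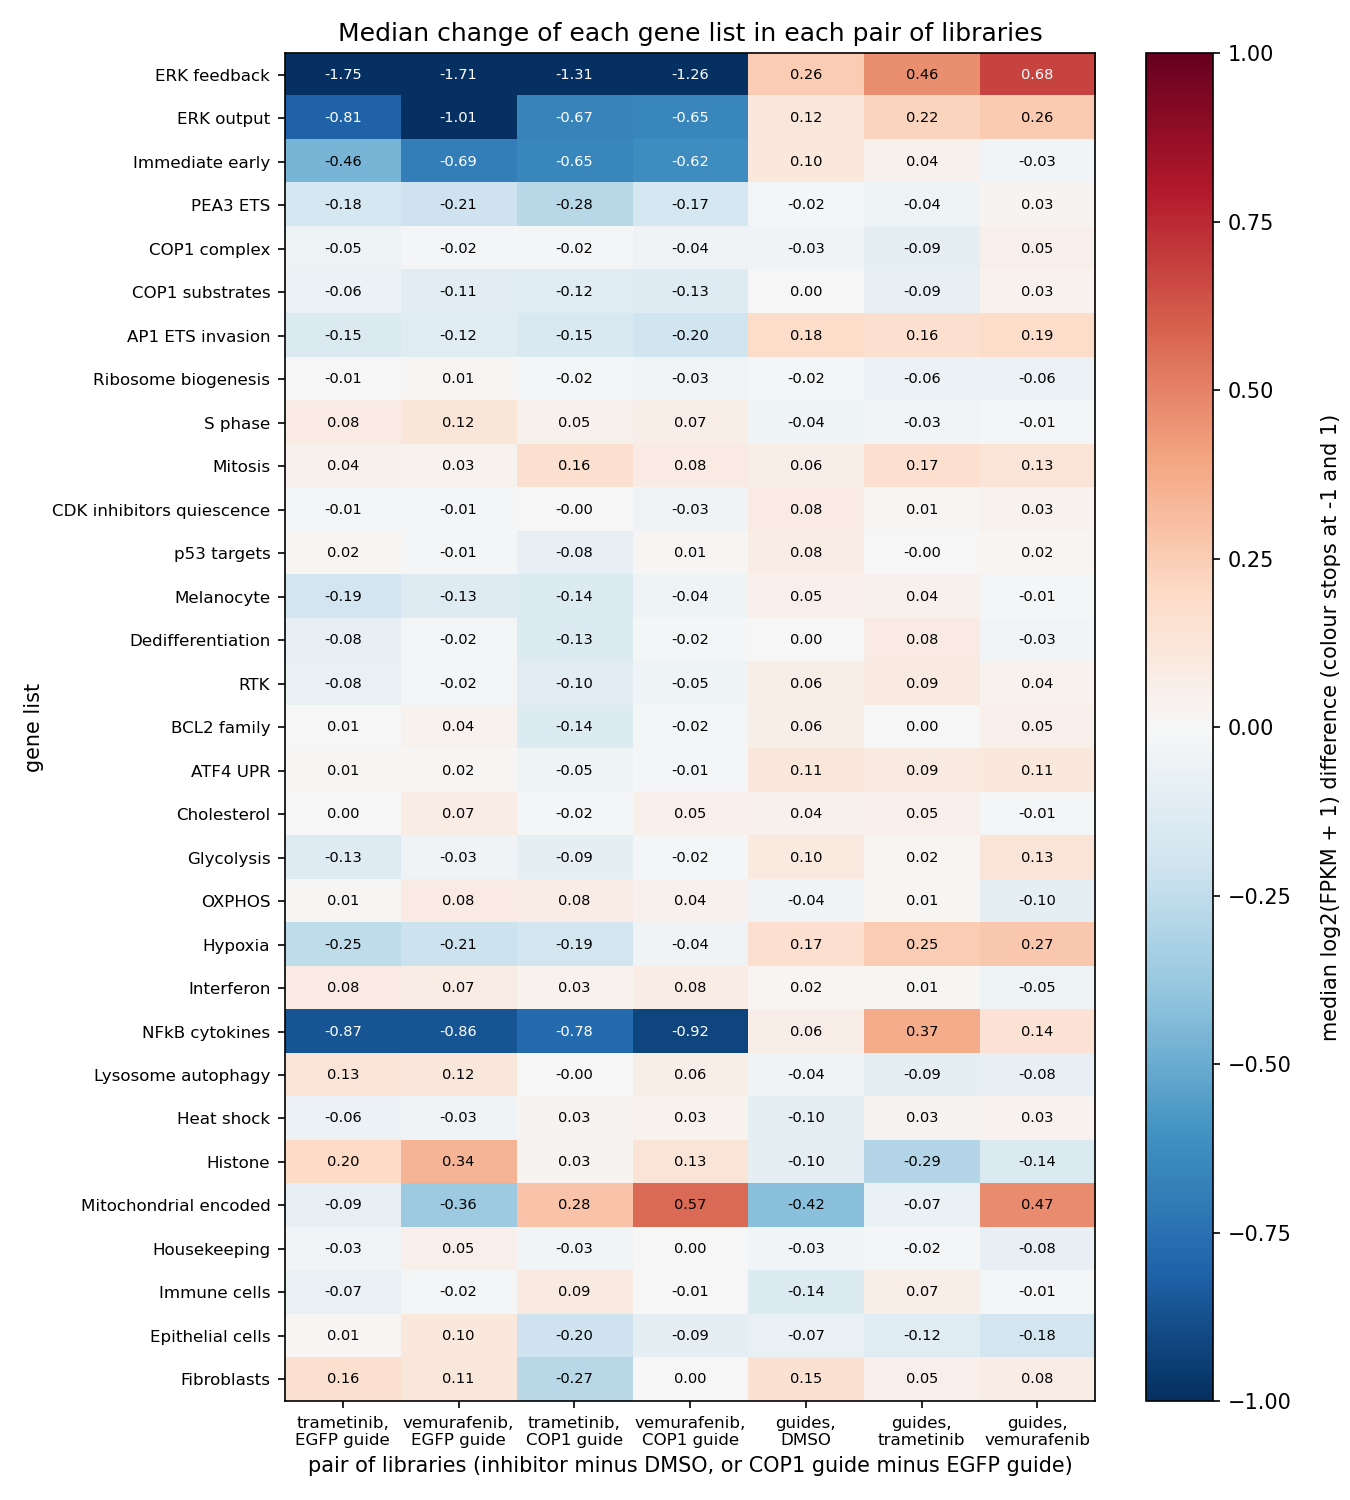
Median log2(FPKM + 1) difference of the members of each of the 31 gene lists (vertical axis) in each pair of libraries (horizontal axis), as colour and printed value, for inhibitor minus DMSO within a guide and COP1 guide minus EGFP guide within a treatment. The ERK feedback list lies between -1.75 and -1.26 for the inhibitors and at 0.26, 0.46 and 0.68 between guides under DMSO, trametinib and vemurafenib.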

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

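The tests on the ERK genes, the mitochondrial transcripts and the genes with jumping values were chosen only after the results had been seen, whereas the regrouping of the libraries had been planned.

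The 148 genes called between guides were set against the other ways to divide the 6 libraries into 3 and 3. Of the 10 splits, 1 gave as many calls, which was the real one, and the highest of the others gave 0. Of the 10 splits 4 divide the 2 libraries of every treatment between the sides, as the real one does, and the other 6 do so for 1 treatment. With so few splits the share cannot fall under 0.05. In the other splits the difference between guides also falls into the residual spread and makes calls harder. Their 0 therefore does not show how many calls would come by chance.

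A first pattern is a positive median difference in response of the ERK lists, 0.21 for ERK feedback genes and 0.056 for other ERK-driven genes, in which 0 of 12 and 0 of 28 genes passed and the adjusted p was 0.883 with an estimated correlation and 0.675 and 0.720 with fry. Library scaling would move genes of like expression alike, and the 2 medians lay above at least 98.7% of random lists matched on expression. The lists were flagged because camera had set them apart from other genes in this same comparison. Their place was thus largely fixed by that choice and cannot decide on scaling. The median difference in response over all 10803 tested genes, which rests on no such choice, was -0.017. The median ratios of the libraries ran from 0.995 to 1.01. These values argue against a factor on a whole library as the source of the 2 positive medians. A weaker inhibition in COP1-guide wells could reduce each response by a common factor. The test took 19 genes that fell by 1 or more with both inhibitors in EGFP-guide cells. At least 8 lay beyond their 95% limits for any factor from 0 to 2, where 0.95 are expected by chance. From 8.75% (EPHA4) to 128% (EGR1) of the response was kept. The limits take their error from the spread between the 2 inhibitors within a guide. They assume that the lone DMSO library of each guide, which both responses share, varies no more than that. The genes also come from lists flagged in this same comparison, so 0.95 may be too low a reference. A common factor is therefore argued against only as far as that error holds. An earlier test, in which 4 (21.1%: HBEGF, SPRY4, SH2B3 and EGR1) kept at least 90%, had lain between its bounds of 10% and 25%. Values near the floor cannot be told apart from a difference in response: the 30 ERK-list genes with at least 5 FPKM in all 4 inhibited libraries had a median of 0.13 against 0.098 for all 40 and 0.0046 for the other 10, which goes against a floor, but 20 of the 30 were above 0 (exact 95% binomial interval 47.2% to 82.7%), which covers 50%. With 1 library per combination, a difference between wells that acts unequally on genes and an effect of COP1 loss on these transcripts are confounded, and both stay open.

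A second pattern is in mitochondrially encoded genes, whose response to the inhibitors differed between guides by a median of 0.63. Relative to the mean of the libraries their median was 0.13, 0.067 and -0.20 with DMSO, trametinib and vemurafenib for the EGFP guide and -0.28, 0.0045 and 0.27 for the COP1 guide. A COP1-guide DMSO library with less mitochondrial RNA could give such a difference alone, but the other 5 libraries spread over 0.47, more than the 0.4 set as the bound against it. That spread lies between the 2 vemurafenib libraries. The median differences between guides were -0.42 with DMSO, -0.068 with trametinib and 0.47 with vemurafenib. The DMSO library could thus still give a part of the difference, and the interaction cannot be refitted without it. Differences in RNA extraction or in mitochondrial content between single libraries, and an effect of COP1 loss, were not tested and stay open.

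The last pattern is genes whose values jump between libraries, such as ADAT2, C11orf70, WDR78 and ZNFX1, the gene with the largest rise under vemurafenib. A first definition, a gap of 1.5 log2 units to the nearest library that made up most of the range, found 0 genes, and the definition used here, a residual SD of at least 0.5 log2 units in both models, was chosen after that and found 34. Of these 25 (73.5%) overlapped another annotated gene, against 6333 of 10656 other genes (59.4%; Fisher's exact p = 0.115, two-sided), so a misassignment of fragments between overlapping genes cannot be told apart from chance. Low abundance remains possible for part of them, since their median FPKM was 3.24 against 16.5 for all tested genes, but 11 (32.4%) had a mean of 5 FPKM or more, and this share lies between the bounds set for and against it. No biological explanation was tested for these genes.

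The other lists that stood out for a response that differed between guides had medians of 0.061 (mitosis), 0.093 (hypoxia), 0.084 (NF-kB targets), 0.088 (heat shock) and -0.12 (histones), each called by camera with an adjusted p of 0.883 with an estimated correlation.

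Genes stood out when both inhibitors moved them one way with the EGFP guide and the opposite way with the COP1 guide, a difference that for none of them passed the test by limma, in which 0 genes were called and 324 had an unadjusted p under 0.05, where 540 are expected by chance. The difference in response was -0.19 for ITGB7 and -0.41 for MAF, both lower with the COP1 guide. It was positive for ADAT2 (3.88), UBAP2 (1.39) and LYSMD3 (1.15). It was negative for C11orf70 (-4.28), WDR78 (-2.14), ACHE (-1.69), HIST1H2AM (-1.54), CRIP1 (-1.18), CDR1 (-1.16, with the smallest adjusted p of these genes, 0.558), C1orf122 (-1.08) and SVIL (-1.07). Only named genes were searched, and all of these but ITGB7 and MAF had been named for large differences in this same comparison. A move of any size counted, and some were near 0. WDR78 moved by 0.0061 with trametinib and the EGFP guide. With the COP1 guide ACHE moved by -0.081 with trametinib and -0.025 with vemurafenib, and MAF by -0.021 with vemurafenib.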

How the results depend on the processing

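The refits without each library of the 8 gene lists called for the interaction were chosen only after the results had been seen. All alternatives ran, except that the interaction could not be estimated without either DMSO library. Where a library was left out its combination had none, and the remaining lone libraries are assumed to vary like the other groups. Genes called in a main comparison (148 between guides, 254 and 350 for trametinib and vemurafenib, 47 between guides under inhibitor) kept their sign wherever they were tested. Without a filter on low values the counts were 0 (2433 at an unadjusted p under 0.05 by limma) between guides, 32 for trametinib, 81 for vemurafenib and 0 (1795) between guides under inhibitor. Without a trend they were 31 between guides and 30 between guides under inhibitor, and without the treatment term 24 between guides. A pseudocount of 0.1 gave 142, 254, 345 and 47, a mean of at least 5 FPKM 190, 263, 328 and 47, and rescaling 128, 245, 340 and 47. Leaving out 1 library gave 2 to 122 between guides, 74 to 349 for trametinib, 150 to 312 for vemurafenib, 0 to 16 for trametinib against vemurafenib, 0 to 136 between guides under inhibitor and 0 to 9 for the interaction. List calls numbered 0 with an estimated correlation, which leaves 2 degrees of freedom, in all 5 comparisons that had any. With fry they numbered 0 between guides, 0 for the interaction and 3 between guides under inhibitor. In the retained output, which does not subtract the difference between guides under DMSO, the shares above 0 stayed similar. They were 68.4% to 79.3% of genes chosen as lowered by vemurafenib and 71.7% to 79.7% of those chosen by trametinib. The low ends came with a threshold of 0.58 log2 units in place of 1, where the medians were 0.16 and 0.19 against 0.29 and 0.41. For genes chosen as raised the shares were 31.4% to 40% and 28.6% to 47.1%, and the medians, -0.32 and -0.31 as reported, were -0.15 and -0.18 with a pseudocount of 0.1, -0.18 and -0.15 with the threshold of 0.58, and -0.48 for trametinib with a mean of at least 5 FPKM. Of 952 refits of named genes 802 kept sign and side of the threshold, 119 lost and 25 gained a call and 6 changed sign, and of 320 refits of list medians 262, 21, 15 and 22. The sign changes of genes, none called, came without either DMSO library between guides for ETV5 (-0.0052, range over left-out libraries -0.0052 to 0.099) and EGR1 (-0.15, to 0.29), and for RFWD2 without the EGFP-guide vemurafenib library for vemurafenib (-0.073, to 0.18) and without the COP1-guide trametinib library for trametinib (-0.095, to 0.15).

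Among lists, with the range over left-out libraries, mitochondrially encoded genes changed sign between guides after rescaling (0.0075) and without either DMSO library (0.18, called; -0.24 to 0.18), for trametinib without the COP1-guide DMSO library (-0.21, called; to 0.43), for vemurafenib without that library (-0.21, called) or the COP1-guide vemurafenib library (-0.26, called; to 0.47), and for trametinib against vemurafenib without the COP1-guide trametinib (0.019) or vemurafenib library (0.35, called; -0.37 to 0.35). Heat-shock genes, not called, changed sign between guides after rescaling (0.0039) and without either DMSO library (-0.039 to 0.031), for trametinib without the EGFP-guide DMSO or trametinib library (-0.055 to 0.024), and for vemurafenib after rescaling (-0.0087) and without the EGFP-guide vemurafenib (-0.017) or COP1-guide DMSO library (-0.046 to 0.068). For trametinib against vemurafenib, ERK feedback (-0.0058 and -0.018 without the EGFP-guide vemurafenib and COP1-guide trametinib libraries; to 0.27), ERK output (-0.023 without the former; to 0.097) and NF-kB genes (0.045 and 0.0036 without the EGFP-guide trametinib and vemurafenib libraries; from -0.060) changed sign, as did the hypoxia list for the interaction (-0.00031 without the COP1-guide vemurafenib library; to 0.13). The cause was not tested.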

Other observations

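The tests of NRF2 targets and of genes beside RFWD2 were set after the lower antioxidant genes and the lower RFWD2 had been seen, but before their own results were.

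Several groups that camera did not call had small medians, over members that in part moved both ways. Under vemurafenib the median log2 change was -0.015 for ribosome biogenesis, 0.045 for cell-cycle inhibitors, 0.0097 for p53 targets (mean -0.081), 0.0031 for ATF4 and unfolded protein response genes, 0.062 for cholesterol synthesis, 0.075 for interferon-stimulated genes, 0.10 for lysosome and autophagy genes and 0.023 for housekeeping genes, and camera called none of them in any of the 6 comparisons. Single members did change: TXNIP rose by 1.29 and SESN1 by 0.60 among the cell-cycle inhibitors, and the p53 target GDF15 fell by 1.99. Between guides the same lists had medians of -0.049, 0.033, 0.027, 0.068, 0.014, -0.044, -0.027 and -0.064. Adjusted over the list alone, 8 ATF4 and unfolded protein response genes of 20 were higher between guides and 5 lower, with the median above 99.6% of random lists matched on expression, and 2 were higher and 3 lower under vemurafenib. Under vemurafenib 3 of 15 cell-cycle inhibitors were higher and 3 lower, and 3 of 18 p53 targets higher and 5 lower, adjusted in the same way. The lysosome median under vemurafenib also lay above 99.6% of random lists, with 0 of 21 genes past the test by either adjustment. CDKN1C, which encodes the cell-cycle inhibitor p57, rose by 0.64 with the COP1 guide, CHAC1 rose by 0.65 and the amino acid transporter SLC7A5 fell by 0.37. Of the markers of other cell types, 4 of 18 immune, 5 of 15 epithelial and 4 of 12 fibroblast genes reached the level for testing, with medians between guides of -0.086, -0.14 and 0.16 and none called by camera.

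Lower antioxidant genes with the COP1 guide, such as FTH1, OSGIN1 and TXNRD1 (-0.35), raised the hypothesis that targets of the transcription factor NRF2 are lower as a group. Of 25 other listed NRF2 targets 24 were tested, and their median log2 change was -0.082, with 18 below 0, 0 called by limma and a percentile of 0.7 among random lists matched on expression. The percentile met the bound set for the hypothesis and the median did not, so it may hold in part and these data do not decide it.

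A loss of the chromosome region around the guide's target could also lower RFWD2. The 20 tested genes on either side had a median log2 change between guides of -0.0065, with 20 of the 40 below 0 and 1 called, RASAL2 (-0.63). This argues against a loss of the whole stretch in most cells. The nearest genes on the side of RASAL2 were PAPPA2 (-0.092), ASTN1 (0.043), RASAL2, C1orf220 (-0.063) and RALGPS2 (-0.30). A median over both sides would not show a shorter loss or a loss on a single side, which was not tested.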
